A study of Rattus norvegicus with 20 samples.

How the data were processed

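Messenger RNA 3' ends were sequenced in 20 libraries of cultured rat hippocampal neural stem cells, with Lexogen's QuantSeq chemistry in its low-input form, per the labels. The authors deposited a table of whole-number counts of reads per gene, with no normalization, for 32623 Ensembl gene IDs. The submitters' processing notes name Bowtie2, Subread and featureCounts and the genome build Rnor_6.0. The versions, the strand setting, the read trimming and the treatment of reads that map to several places are not given in the sources used here. Reads shared by near-identical gene copies, and reads of genes that overlap on either strand, may therefore be counted for the wrong gene. Counts of 3' ends do not grow with transcript length, so no length correction was applied.

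Each row of the count table was tied to its library through the well named in that library's labels, and all 20 wells had a library. No other per-sample column was present. Totals ran from 696463 reads (Wnt3a, 1 d) to 5935681 (unstimulated optoWnt cells, 3 d). A count of 0 in the shallowest library allows a level of up to 4.21 CPM (reads of a gene scaled to a common TMM-scaled library total), the level of 3 counts, against 0.513 CPM in the deepest. These floors cover counting error only, since the reads were not collapsed by molecular identifiers here.

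Libraries were grouped by the treatment profile in the labels. This gave 8 profiles: no stimulus at 0, 3 and 5 d (2 libraries each), stimulus ON for 1 d and for 3 d (3 each), ON for 5 d (2), and 1 d ON followed by 1 d or 2 d OFF (3 each). The libraries within a profile differ in genotype (wild-type or optoWnt) when unstimulated and in the inducer (CHIR99021, Wnt3a or light) when stimulated. No exact combination of profile, genotype and inducer was sequenced more than once, and the labels do not state whether libraries came from separate cultures. The p-values therefore measure the spread between these libraries after additive terms for inducer and genotype, and that spread includes any response that differs between inducers. Within profiles, Pearson's r of log2 CPM across genes ran from 0.794 to 0.975 over 16 pairs, and the lowest chi-square per degree of freedom was 6.6, so no pair agreed within sampling noise.

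The main test was edgeR 4.0.16's quasi-likelihood test (R 4.3.3, limma 3.58.1) on the deposited counts, with TMM scaling and filterByExpr by profile, which kept 12190 genes. One additive model with 11 coefficients (8 profiles, genotype and inducer) was fitted to all 20 libraries and left 9 residual degrees of freedom. Inducer was coded to sum to 0 over the 3 inducers, so a profile estimate is a mean over inducers. Light was not sequenced at 5 d ON, so its share of that estimate is extrapolated from its other profiles by the additive model. Each inducer's own sustained effect came from a model of the 9 libraries at 3 and 5 d that were unstimulated or constantly stimulated (day, genotype and inducer, 11566 genes, 3 residual degrees of freedom). The inducer by withdrawal interaction came from the 12 stimulated libraries of 1 to 3 d (11564 genes, 4 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are referred to as called. The common biological coefficient of variation was 0.418. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. CPM values used TMM-scaled library sizes, and means are given with the SD over libraries.

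The deposited table pairs no gene ID with a symbol, and the gene table provided with it (another assembly of the rat genome) carries no Ensembl IDs, so 0 IDs were matched. The 23 gene lists fixed before the data were examined, the tests planned on them and the part of the naming rule that relies on 16 symbols were therefore not run. The remaining part of the naming rule was kept without its condition on symbols: the largest rises and falls among called genes with a mean of at least 5 CPM over both arms and arms that do not overlap. At most 2 IDs per direction are printed for a comparison, and IDs of comparisons with few calls fall outside this rule where stated. A fold against an arm in which every library had a count of 0 is given as a lower bound, against 3 counts over the reads of that arm. With 1 to 3 counts in an arm, the ratio of pooled counts over reads is given with an exact 95% Poisson interval, which covers counting error only.

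Sets of genes took the place of the lists. Of the kept genes, 213 were at least 2-fold higher, and 196 at least 2-fold lower, in both libraries of 5 d ON than in both unstimulated libraries of 5 d. Another 368 and 183 were the genes called higher and lower at 5 d than at 0 d without a stimulus. These sets were chosen after the data were seen and on some of the same libraries. For each library, a set's score is the median over its genes of the log2 CPM (prior count 2) minus the mean of a reference pair, unstimulated 3 d for the 5 d sets and 0 d for the time sets. Each score was ranked among 10000 random gene lists of the same size matched on expression in 20 bins. The ranks are not used below. Over the 213 genes even the reference libraries, with scores of -0.08 (wild-type) and 0.08 (optoWnt), ranked at percentiles 0.1 and 99.8. Set scores of the 6 withdrawn and the 6 constantly stimulated libraries of 1 to 3 d were compared by an exact two-sided permutation test within inducer (216 arrangements, smallest possible p 0.0093).

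The fits were tested on simulated counts with the observed library sizes and dispersions and with 100 genes changed 2-fold and 100 changed 4-fold. Each gene had its mean over all libraries in every library, and each comparison was drawn once. No other difference between profiles, inducers or libraries was simulated, so the shares hold for that setting only. For the average sustained comparison, 0% of the 2-fold and 33% of the 4-fold genes were recovered among 11906 genes tested. The corresponding shares were 2% and 56% for light against CHIR99021 (11884 genes), 1% and 32% for 1 d ON 2 d OFF against 3 d ON (11876 genes), 0% and 17% for genotype (11870 genes), 0% and 2% for 5 d against 0 d (11878 genes) and 0% and 1% for CHIR99021 alone (11540 genes). At most 2 unchanged genes were called in each simulation.

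Alternatives listed before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0 with the same model, leaving out each library in turn, fitting only the arms compared, leaving out the 3 wild-type libraries and omitting the inducer term. Alternatives added after the data were seen were leaving out 6 libraries that stand apart on the first principal component, using that component's score as a covariate, and, for the sets, a 4-fold gap, RLE size factors, a prior count of 0.5 and leaving out each library. DESeq2 applied its own filter in each comparison, so its counts rest on other sets of genes than those of edgeR. Figures were drawn with matplotlib 3.10.9.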

Results

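The 20 libraries profiled messenger RNA in neural stem cells from the hippocampus of adult Fisher 344 rats. The cells were moved to a basal medium with little serum, in which they differentiate, and the canonical Wnt pathway was switched on by one of 3 inducers. CHIR99021 is a small-molecule inhibitor of GSK-3, the kinase that marks β-catenin for destruction. Wnt3a is a Wnt ligand, given at 100 ng/mL. The third inducer was light acting on optoWnt, a light-sensitive fusion of the Wnt co-receptor LRP6 that clusters under blue illumination. The stimulus was given for 1, 3 or 5 d without interruption (ON), or for 1 d followed by 1 or 2 d without it (OFF). Every stimulated library, with any inducer, came from optoWnt cells. Wild-type and optoWnt cells labelled as given no inducer were sequenced at 0, 3 and 5 d and are called unstimulated here. The titles of the 3 and 5 d libraries of both genotypes also carry the word ON, and whether these cells were illuminated is not given in the sources used here. If they were, the optoWnt baselines of 3 and 5 d were light-stimulated, which bears on the genotype comparison, on every comparison with unstimulated 3 or 5 d and on the set scores. Light was not sequenced at 5 d ON. Total reads per library ran from 696463 to 5935681. Genes are given by Ensembl ID because the files used here do not pair IDs with symbols, and no pathway or cell type can be named from them.

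Across all 20 libraries, the first principal component of log2 CPM held 29.4% of the variance and did not follow the treatment profile. On it, 6 libraries (wild-type 0 d, wild-type 5 d, Wnt3a 5 d ON, light 3 d ON, CHIR99021 1 d ON 2 d OFF and Wnt3a 1 d ON 2 d OFF) scored -41.5 or lower, while the other 14 scored 8.9 or higher. The 6 were picked by these scores, which rest on the same genes. In each of the 6, 74 genes were at least 2-fold lower than in each of the 14, with a median log2 difference of -2.79, and 0 genes were higher by that margin. ENSRNOG00000031960 ranged from 0 to 8.94 CPM in the 6 libraries and from 57.5 to 143 CPM in the others. The second component held 16.3% and placed the 0 d libraries (-65.5 and -52.4) opposite CHIR99021 at 3 and 5 d ON (73.5 and 55.4).

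**Figure D1:**
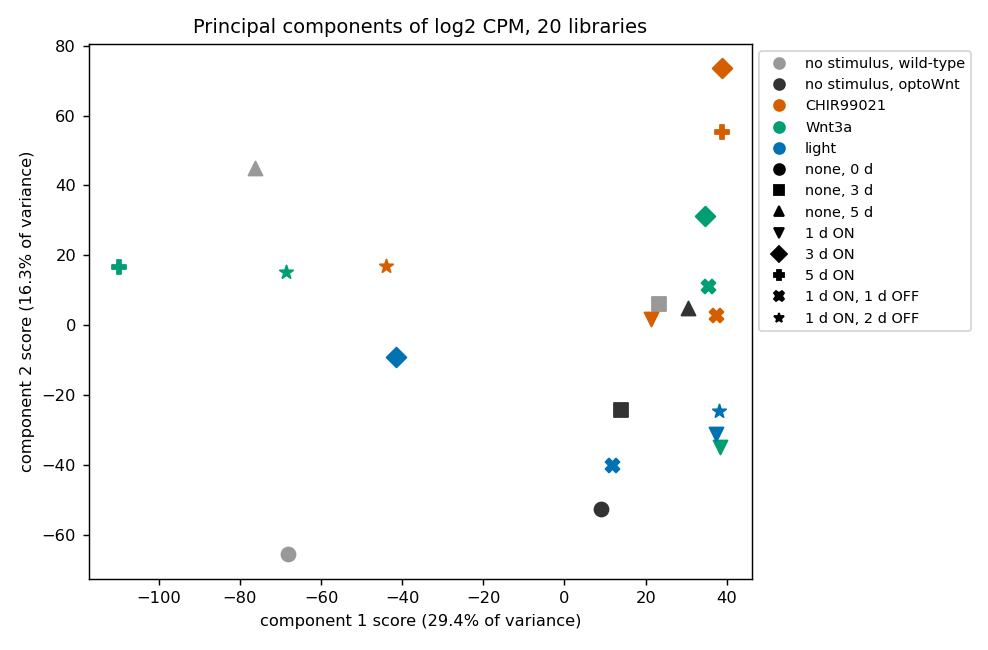
Each point is 1 of the 20 libraries, placed by its scores on the first (x axis) and second (y axis) principal component of log2 CPM; colour gives the inducer or genotype and shape the treatment profile. The 6 libraries at -41.5 or lower on the first component come from 5 profiles, and CHIR99021 at 3 d ON has the highest second score, 73.5.

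The first comparison asks whether carrying the optoWnt construct changed unstimulated cells. With 3 optoWnt and 3 wild-type libraries, 0 of 12190 genes were called by edgeR's quasi-likelihood test (smallest adjusted p 0.2). Of the 12190, 956 had an unadjusted p under 0.05 where 610 would by chance. DESeq2 called 22 of the 1807 genes left by its own filter. Of the 3 wild-type libraries, 2 were among the 6 with low first component scores, against 0 of the 3 optoWnt libraries.

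Without a stimulus, the cells' transcripts changed widely over 5 d in the differentiation medium. At 5 d, 368 genes were higher and 183 lower than at 0 d (2 libraries against 2, edgeR adjusted p under 0.05), with a median absolute log2 fold change of 2.6 among these 551 (2.59 with the 25 genes without a read in 1 arm set to their lower bound). At 3 d, 159 were higher and 93 lower than at 0 d, with a median absolute log2 fold change of 2.84. ENSRNOG00000009660 had 0 counts in both libraries of 0 d and reached 17.8 and 20.9 CPM at 3 d and 44.5 ± 5.88 CPM (SD, n = 2) at 5 d, at least 83.1-fold higher than at 0 d (edgeR adjusted p = 0.0091). This call was lost without wild-type 0 d (edgeR adjusted p = 0.17), wild-type 5 d (0.078) or optoWnt 0 d (0.073). ENSRNOG00000055161 fell from 64.1 (wild-type) and 15.3 CPM (optoWnt) to 0 counts in both libraries, at least 77.4-fold lower (edgeR adjusted p = 0.016). Without wild-type 0 d this was at least 29.9-fold and was not called (edgeR adjusted p = 0.26), and the call was also lost without wild-type 5 d (0.21) or optoWnt 5 d (0.071). ENSRNOG00000053898 fell from 40.9 (wild-type) and 5.11 CPM (optoWnt) to 0 counts, at least 44.9-fold lower (edgeR adjusted p = 0.016). Without wild-type 0 d this was at least 9.96-fold and was not called (edgeR adjusted p = 0.3), and the call was also lost without wild-type 5 d (0.24) or optoWnt 5 d (0.055). ENSRNOG00000048102 met the same rule (edgeR adjusted p = 0.016) with 0.511 and 141 CPM at 5 d, so its rise rests on the wild-type library, and the call was lost without wild-type 5 d (edgeR adjusted p = 0.6) or wild-type 0 d (0.62).

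The 5 d count fell to 32 when the wild-type 0 d library was left out, to 67 without the wild-type 5 d library, to 307 without the optoWnt 0 d library and to 9 without all 3 wild-type libraries, where each arm has 1 library. DESeq2 called 1251 genes, 548 of them among the 551. The 3 d count fell to between 17 (without wild-type 0 d) and 75 (without optoWnt 3 d) when any of its 4 libraries was left out, with 43 without wild-type 3 d and 46 without optoWnt 0 d, and it was 2 without all 3 wild-type libraries.

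Constant stimulation was compared with no stimulus over 3 and 5 d, averaged over days and inducers. The share of light at 5 d was extrapolated by the model, since light was not sequenced there. Of 12190 genes, 15 were higher and 9 lower in the 5 stimulated than in the 4 unstimulated libraries (edgeR adjusted p under 0.05), with a median absolute log2 fold change of 3.06. The stimulated libraries were all optoWnt and the unstimulated ones of both genotypes. Genotype is a term of the model, but the CPM means below do not allow for it. ENSRNOG00000026053 rose from 2.54 ± 1.52 CPM (SD, n = 4) to 118 ± 87.5 CPM (SD, n = 5), a log2 fold change of 5.66 (SE 1.01, edgeR adjusted p = 0.043). It stood at 34.4 CPM or more in each of the 5 stimulated libraries and at 4.14 CPM or less in each unstimulated one. ENSRNOG00000040287 rose from 2.33 ± 2.28 to 80.9 ± 82.4 CPM (SD, n = 4 and 5), a log2 fold change of 5.22 (SE 0.95, edgeR adjusted p = 0.043). Under light at 3 d ON it stood at 8.8 CPM, close to the highest unstimulated value of 5.7 CPM. ENSRNOG00000016516, an abundant transcript, fell from 4290 ± 1060 to 1120 ± 1270 CPM (SD, n = 4 and 5), a log2 fold change of -3.07 (SE 0.52, edgeR adjusted p = 0.04). That fold change is a model estimate and not the ratio of the printed means. The fall was uneven, with 142 and 92.9 CPM at 3 and 5 d of CHIR99021 and 357 CPM at 5 d of Wnt3a. At 3 d ON, Wnt3a (2660 CPM) and light (2350 CPM) lay close to the lowest unstimulated value, 2960 CPM. ENSRNOG00000010263 fell from 10.3 ± 2.61 to 1.24 ± 0.999 CPM (SD, n = 4 and 5), a log2 fold change of -3.39 (SE 0.62, edgeR adjusted p = 0.043). All 4 IDs lost their call (edgeR adjusted p from 0.06 to 0.47) when any of the 4 unstimulated libraries, Wnt3a 5 d ON or light 3 d ON was left out. All but ENSRNOG00000016516 also lost it without CHIR99021 3 d ON (0.084), and ENSRNOG00000016516 and ENSRNOG00000010263 without CHIR99021 5 d ON (0.079 and 0.1).

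The 24 calls depended on single libraries. Left out in turn, the optoWnt 3 d and optoWnt 5 d unstimulated libraries each left 0 calls, wild-type 5 d left 3, wild-type 3 d left 5, light 3 d ON and Wnt3a 5 d ON left 4 each, CHIR99021 3 d ON left 9, and Wnt3a 3 d ON raised the count to 98. DESeq2 called 274, fits without the inducer term, of the arms alone or without the wild-type libraries called 0, and leaving out the 6 libraries with low first component scores gave 127, of which 21 were among the 24. By single day, edgeR called 0 genes at 3 d (3 libraries against 2, smallest adjusted p 0.13, 1031 with an unadjusted p under 0.05, DESeq2 113) and 0 at 5 d (2 against 2, smallest adjusted p 0.066, 961 unadjusted, DESeq2 100).

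By inducer, constant CHIR99021 gave 201 called genes against the 4 unstimulated libraries of 3 and 5 d, 105 higher and 96 lower, with a median absolute log2 fold change of 3.86 (edgeR, n = 2 and 4). ENSRNOG00000013859 stood at 172 ± 16 CPM (SD, n = 2) under CHIR99021 and at 0.321 ± 0.49 CPM (SD, n = 4) without it, with 1389 counts against 3, a ratio of 906 with a 95% interval of 309 to 4400 from counting alone (edgeR adjusted p = 0.004). In the other libraries of 3 or 5 d ON it reached 2.75 and 6.66 CPM under Wnt3a and 0.8 CPM under light. ENSRNOG00000006723 stood at 25.8 ± 1.46 CPM (SD, n = 2) against 0 counts in all 4 unstimulated libraries, at least 135-fold higher (edgeR adjusted p = 0.02). DESeq2 did not call this ID (DESeq2 adjusted p = 0.35). ENSRNOG00000009660, which rose with time without a stimulus, had 0 counts under CHIR99021 at 3 and 5 d against 31.9 ± 15 CPM (SD, n = 4), at least 85.3-fold lower (edgeR adjusted p = 0.017). ENSRNOG00000000775 had 0 counts against 17.5 ± 7.78 CPM (SD, n = 4), at least 46.8-fold lower (edgeR adjusted p = 0.015). Without CHIR99021 3 d ON none of these 4 IDs was called (edgeR adjusted p of 0.056, 0.28, 0.24 and 0.23 in the order named), and without CHIR99021 5 d ON only the first was, the others having an adjusted p of 0.087, 0.096 and 0.11.

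The CHIR99021 count was 0 without its 3 d library and 45 without its 5 d library, 97 without wild-type 5 d, 415 without Wnt3a 3 d and 445 without Wnt3a 5 d, and DESeq2 called 616. Constant Wnt3a (2 libraries) gave 1 call, ENSRNOG00000026053, at a log2 fold change of 5.54 (SE 0.6, edgeR adjusted p = 0.049), named here after its values were seen. That call was lost when wild-type 3 d, wild-type 5 d, optoWnt 3 d, CHIR99021 3 d, CHIR99021 5 d or light 3 d was left out (0 calls each), when Wnt3a 5 d was left out (1 call, of another gene) and when the first component was a covariate. Leaving out optoWnt 5 d gave 3 calls, and DESeq2 gave 36 and the fit with no low-count filter 88. Constant light, with a single library, gave 0 calls by edgeR (800 with an unadjusted p under 0.05, smallest adjusted p 0.23) and 8 by DESeq2, and 108 by edgeR with no low-count filter and 2 without optoWnt 5 d. The lone light library is assumed to vary like the others, and a difference between these 3 counts is no test of a difference between inducers.

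**Figure D2:**
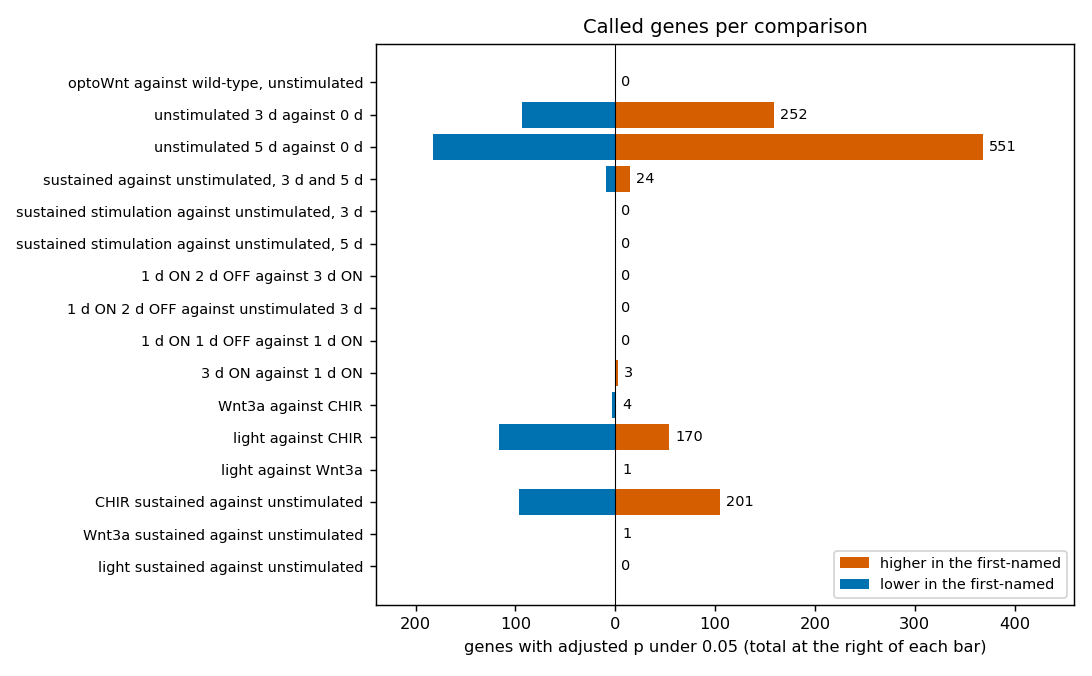
Bars give the number of genes with an adjusted p under 0.05 in each comparison (x axis), to the right of 0 for genes higher and to the left for genes lower in the condition named first (y axis), with the total printed. Time without a stimulus gave 551 calls at 5 d, and the comparisons of withdrawn with constant stimulation gave 0.

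The 213 genes that were higher at 5 d ON were followed through the earlier libraries, relative to unstimulated 3 d. Under CHIR99021 their median log2 difference was 0.83 at 1 d and 1.77 at 3 d ON, against 2.23 at 5 d, where they were chosen. Under Wnt3a the medians were 0.07, 0.38 and 2.13, the last again by choice, and under light 0.29 at 1 d and 0.85 at 3 d. Unstimulated cells at 0 d stood at 0.72 (wild-type) and 0.21 (optoWnt), so the lower Wnt3a and light values lie within the unstimulated range. The upper end of that range rests on wild-type 0 d alone. The other unstimulated libraries stood at 0.21 or lower, below Wnt3a at 3 d ON (0.38) and light at 1 d ON (0.29). No light library entered the choice of genes, so lower values under light are partly built in. After 1 d ON and 1 d OFF the medians were 0.64 for CHIR99021, 0.39 for Wnt3a and 0.14 for light, and after 2 d OFF they were 1.11, 0.94 and -0.16. The CHIR99021 and Wnt3a libraries of 2 d OFF and the light library of 3 d ON are among the 6 with low first component scores. So are wild-type 0 d and, of the libraries on which the genes were chosen, wild-type 5 d and Wnt3a 5 d ON.

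The 196 genes that were lower at 5 d ON moved the other way. Their medians under CHIR99021 were -0.83, -1.54 and, where chosen, -2.06 at 1, 3 and 5 d ON. Under Wnt3a they were -0.4, -0.07 and, where chosen, -1.66, and under light -0.58 and -0.79. Cells at 0 d stood at -1.57 (wild-type) and -0.84 (optoWnt) and unstimulated 5 d cells at 0.21 and 0.14, so the 0 d medians lay below those at 3 and 5 d without a stimulus. After 1 d OFF the medians were -0.51 for CHIR99021, -0.21 for Wnt3a and -0.29 for light, and after 2 d OFF they were -0.91, -0.71 and 0.22.

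**Figure D3:**
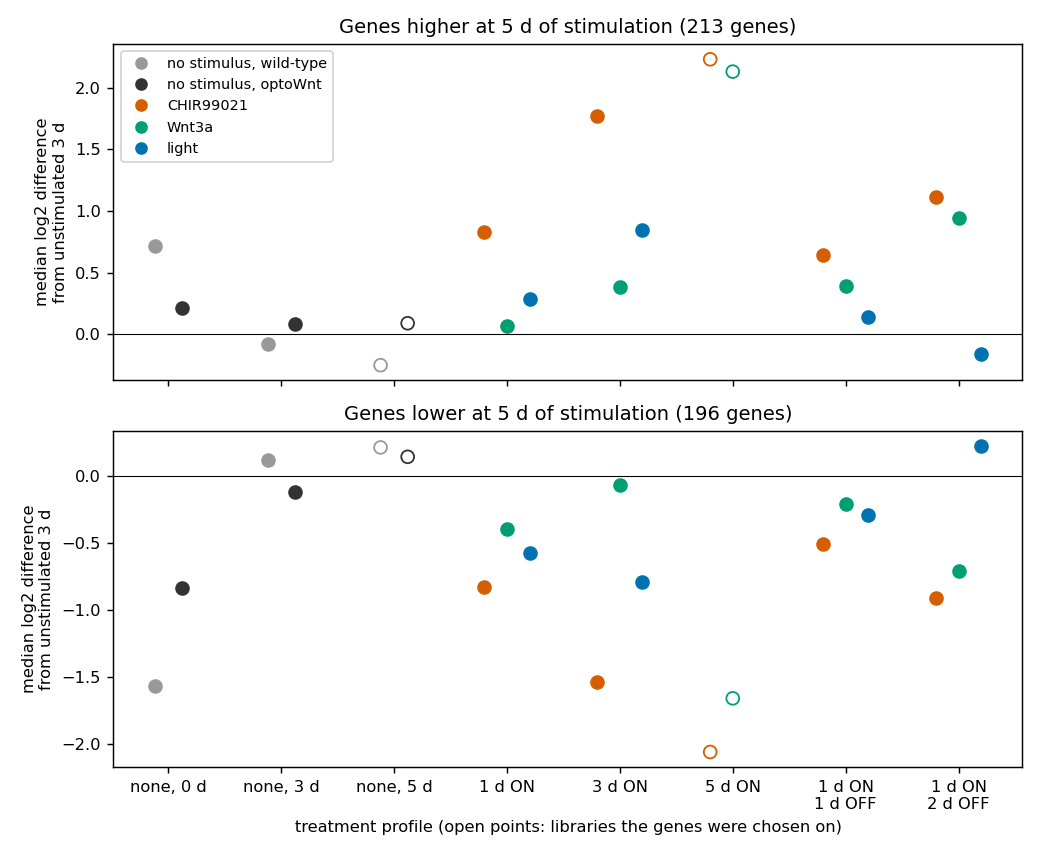
Points give, for each library, the median log2 difference from the mean of the unstimulated 3 d libraries (y axis) over 213 genes higher (top) and 196 genes lower (bottom) at 5 d ON, by treatment profile (x axis) and inducer or genotype (colour). Open points are the libraries on which the genes were chosen. At 3 d ON, CHIR99021 lies furthest from 0, at 1.77 and -1.54.

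The main question of the design is whether a stimulus withdrawn after 1 d leaves cells different from those kept under stimulation. At day 3, 1 d ON 2 d OFF differed from 3 d ON in 0 of 12190 genes (3 libraries against 3, smallest edgeR adjusted p 0.29), with 1095 genes at an unadjusted p under 0.05. DESeq2 called 43 genes, the first component as a covariate gave 21 and the fit with no low-count filter 17. At day 3, the withdrawn libraries also differed from the 2 unstimulated ones in 0 genes (smallest edgeR adjusted p 0.64, 898 unadjusted, DESeq2 0). One day of withdrawal against 1 d ON gave 0 genes (238 unadjusted, fewer than the 610 of chance; DESeq2 3), in a comparison in which day and withdrawal change together. The change on withdrawal was not called as differing between inducers for any of 11564 genes (edgeR interaction, smallest adjusted p 0.16, 400 unadjusted, DESeq2 11 of 7303 genes). That interaction count was 88 with no low-count filter and 3 with the component as a covariate, so the 0 depends on these settings. Leaving out the 6 libraries with low component scores left light as the only inducer at 2 d OFF. Counts of those fits are therefore not set beside the main ones here and are no measure of an effect. In simulated counts without other differences between libraries, 32% of genes changed 4-fold and 1% of those changed 2-fold were recovered for 2 d OFF against 3 d ON. Changes of these sizes could therefore have gone uncalled.

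Over whole sets, the 6 withdrawn libraries of 1 d ON were set against the 6 libraries of 1 or 3 d ON within inducer. The genes higher at 5 d ON had a mean score of 0.51 ± 0.48 after withdrawal and 0.7 ± 0.61 under constant stimulation (SD, n = 6 each, exact permutation p = 0.47, adjusted 0.63). The genes lower at 5 d ON scored -0.4 ± 0.4 and -0.7 ± 0.49 (SD, n = 6 each, exact permutation p = 0.21, adjusted 0.42). The 368 genes that rose with time without a stimulus scored 1.87 ± 0.2 after withdrawal and 1.56 ± 0.35 under stimulation, relative to 0 d (SD, n = 6 each, exact permutation p = 0.11, adjusted 0.42). The 183 genes that fell with time scored -1.91 ± 0.2 and -1.89 ± 0.29 (SD, n = 6 each, exact permutation p = 0.88, adjusted 0.88). None of these 4 differences passed the threshold. The constant arm includes 1 d ON libraries, which were younger than any withdrawn library.

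Levels of 3 IDs named above are given for this comparison. ENSRNOG00000026053 stood at 120, 38 and 34.4 CPM at 3 d ON under CHIR99021, Wnt3a and light, and at 13.5, 18.4 and 4.63 CPM after 1 d ON 2 d OFF. ENSRNOG00000016516 stood at 142, 2660 and 2350 CPM at 3 d ON in the same order and at 738, 1090 and 5370 CPM after 2 d OFF. ENSRNOG00000009660 stood at 0, 13 and 6.8 CPM at 3 d ON and at 4.77, 8.07 and 15.4 CPM after 2 d OFF. These differences were not called.

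**Figure D4:**
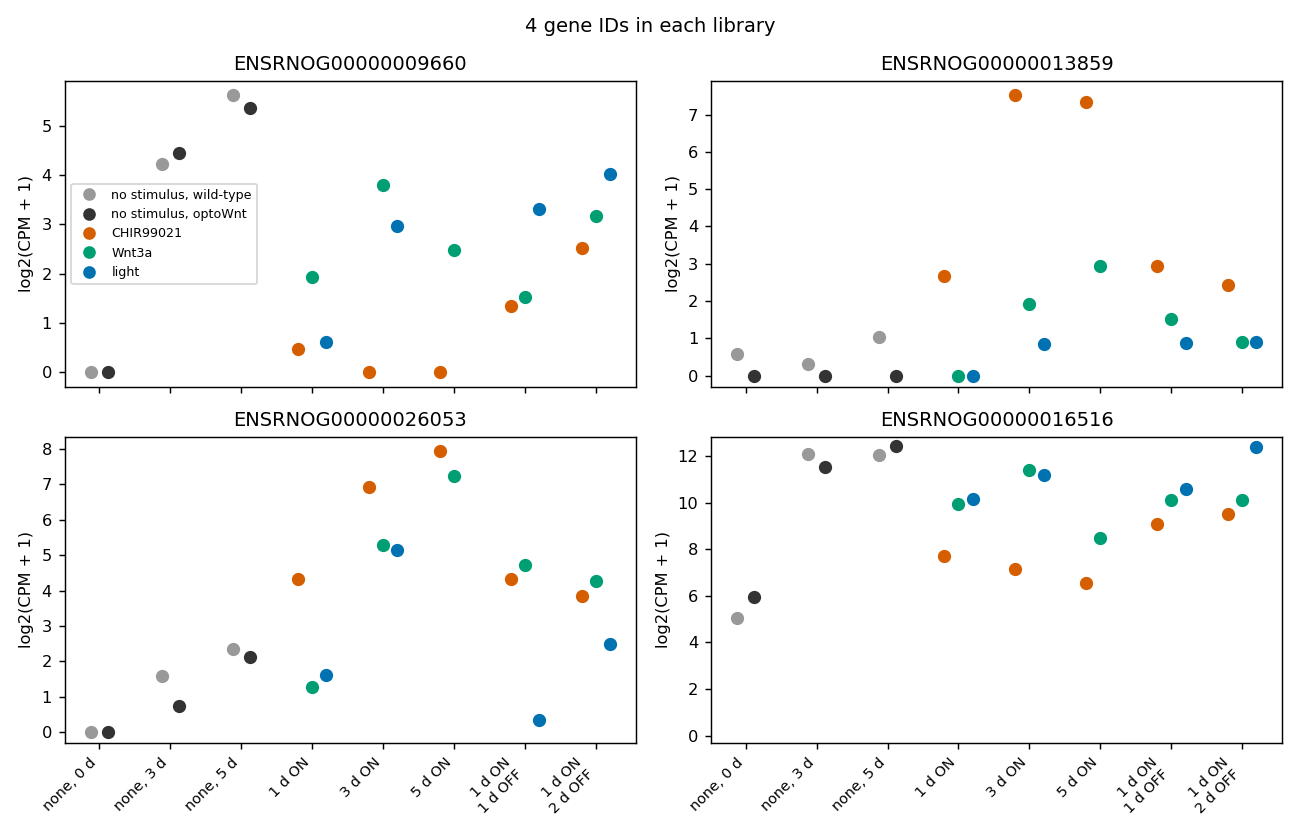
Points give the level of 4 gene IDs in each library as log2(CPM + 1) (y axis) by treatment profile (x axis), coloured by inducer or genotype. ENSRNOG00000013859 exceeds 100 CPM at 3 and 5 d of CHIR99021 (183 and 161 CPM) and stays at or below 6.66 CPM in every other library.

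Under constant stimulation, 3 genes were higher at 3 d than at 1 d ON and 0 were lower (3 libraries against 3, edgeR). ENSRNOG00000005392 rose from 10.6 ± 9.99 to 212 ± 290 CPM (SD, n = 3 each), a log2 fold change of 3.81 (SE 0.57, edgeR adjusted p = 0.042). At 3 d ON it stood at 546 CPM under CHIR99021 and at 51.1 and 38.4 CPM under Wnt3a and light, and without a stimulus at 1.44 and 3.69 CPM at 0 d, 35 and 9.06 CPM at 3 d and 305 and 68.4 CPM at 5 d (wild-type and optoWnt). ENSRNOG00000007367 rose from 1.61 ± 0.414 to 15.6 ± 1.48 CPM (SD, n = 3 each), a log2 fold change of 3.26 (SE 0.51, edgeR adjusted p = 0.049). Without a stimulus it also rose, from 2.89 and 0.852 CPM at 0 d to 15 and 8.38 CPM at 3 d and 62.6 and 34 CPM at 5 d. Day and duration of the stimulus change together in this comparison and there is no unstimulated library of 1 d, so it does not separate them. The calls were 0 when any 1 of the 6 libraries was left out or the inducer term was omitted, and 271 by DESeq2, 377 with the first component as a covariate and 192 without the 6 libraries with low scores.

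The 3 inducers were compared with the treatment profile as a term of the model. CHIR99021 and Wnt3a have a 5 d ON library and light has none. Light differed from CHIR99021 in 170 genes, 54 higher and 116 lower under light (4 libraries against 5, edgeR adjusted p under 0.05), with a median absolute log2 fold change of 1.94. ENSRNOG00000017725 stood at 591 ± 193 CPM (SD, n = 4) under light and 84.2 ± 107 CPM (SD, n = 5) under CHIR99021, a log2 fold change of 3.59 (SE 0.79, edgeR adjusted p = 0.039). ENSRNOG00000016516 stood at 2600 ± 1910 against 344 ± 280 CPM (SD, n = 4 and 5), a log2 fold change of 2.58 (SE 0.46, edgeR adjusted p = 0.019). ENSRNOG00000002728 had 0 counts in all 4 light libraries and 11.9 ± 7.65 CPM (SD, n = 4) in the CHIR99021 libraries of the same profiles, at least 50.2-fold lower under light (edgeR adjusted p = 0.011). CHIR99021 5 d ON, with no light library beside it, stood at 55.2 CPM. ENSRNOG00000008697 stood at 0.1 ± 0.2 CPM against 9.47 ± 7.02 CPM (SD, n = 4 and 5, edgeR adjusted p = 0.007), and over the shared profiles CHIR99021 had 141 counts against 1, a ratio of 94.5 with a 95% interval of 16.7 to 3760 from counting alone. Without CHIR99021 3 d ON none of these 4 IDs was called (edgeR adjusted p of 0.13, 0.076, 0.06 and 0.06 in the order named). The first was also lost without CHIR99021 1 d ON (0.11) or light 1 d ON (0.078), 3 d ON (0.12) or 1 d ON 1 d OFF (0.13). The second was also lost without CHIR99021 1 d ON (0.065) or light 3 d ON (0.075), 1 d ON 1 d OFF (0.067) or 1 d ON 2 d OFF (0.053). The count fell to 6 without CHIR99021 3 d ON, 9 without light 1 d ON 1 d OFF, 13 without light 3 d ON, 32 without CHIR99021 1 d ON and 70 without light 1 d ON. DESeq2 called 736 genes, 169 of them among the 170.

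Wnt3a differed from CHIR99021 in 4 genes, 1 higher and 3 lower under Wnt3a (5 libraries against 5, edgeR adjusted p under 0.05), and 3 of these are named after their values were seen. ENSRNOG00000058645 stood at 49.1 ± 43.5 CPM under Wnt3a and 356 ± 301 CPM under CHIR99021 (SD, n = 5 each), a log2 fold change of -2.93 (SE 0.3, edgeR adjusted p = 0.00078). ENSRNOG00000005392 stood at 46.7 ± 41 against 312 ± 308 CPM (SD, n = 5 each), a log2 fold change of -2.42 (SE 0.38, edgeR adjusted p = 0.046). ENSRNOG00000030515 stood at 225 ± 42.3 against 73.6 ± 41.3 CPM (SD, n = 5 each), a log2 fold change of 1.77 (SE 0.25, edgeR adjusted p = 0.026). The first kept its call with any 1 library left out, the second lost it without any 1 of the 10 (edgeR adjusted p from 0.06 to 0.3), and the third lost it without CHIR99021 1 d (0.09), 3 d (0.24) or 5 d ON (0.13) or 1 d ON 2 d OFF (0.056), or without Wnt3a 1 d (0.12), 3 d (0.14) or 5 d ON (0.13). DESeq2 called 145 genes, and the fit of the arms alone called 0. The count was 1 without CHIR99021 3 d ON or 5 d ON or without Wnt3a 1 d, 3 d or 5 d ON, and 2 without Wnt3a 1 d ON 2 d OFF.

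Light differed from Wnt3a in 1 gene, also named after its values were seen. ENSRNOG00000016930 stood at 169 ± 51.5 CPM (SD, n = 4) under light and 43.3 ± 10.1 CPM (SD, n = 5) under Wnt3a, a log2 fold change of 1.96 (SE 0.25, edgeR adjusted p = 0.014). DESeq2 called 171 genes. The count was 0 without Wnt3a 3 d ON, light 3 d ON, either withdrawn light library or either withdrawn Wnt3a library (edgeR adjusted p from 0.055 to 0.19), and 2 without Wnt3a 5 d ON. The strength at which each inducer activated the pathway is not given in the sources used here, so the comparisons are of the doses and illumination used.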

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

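The test of depth for light against CHIR99021 and the counts of other splits were set before their results were seen. The test of the first component for that comparison, set when its calls with that covariate were already known, the swaps of inducers within profiles and the tests on the first component itself were chosen after results were seen. Light against CHIR99021 was picked out as a tested difference between inducers, with 170 called genes. Of 60 splits of its 9 libraries, drawn from 126 and the real one included, 1 gave as many calls, the highest other count being 47. Most of these splits break the match of inducers by profile, so this share was the wrong bound. Swaps of light and CHIR99021 within their shared profiles keep the match and make 16 splits, too few for a share under 0.05, with 170 calls in the real one and at most 0 in the others. Thinning the light and CHIR99021 libraries of each profile to equal depth left 141 of the 170 genes called, so most calls did not need unequal depth. The median absolute log2 fold change of the 170 genes stayed at 1 times its value. Thinning keeps each gene's expected share of reads, so that ratio was likely in any case and does not test depth. With the first component score as a covariate the median was 0.99 times its value. Low scores fell on both inducers, at light 3 d ON (-41.5) and CHIR99021 1 d ON 2 d OFF (-43.9). The covariate could therefore change little, and this ratio does not decide whether the component contributes. A difference between inducers in strength or in mode of action remains a candidate explanation and was not tested, and leaving out CHIR99021 3 d ON left 6 calls.

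Wnt3a against CHIR99021 was picked out by the same test of a difference between inducers, with 4 genes, and 1 of 60 splits gave as many, the highest other count being 0. The swaps within profiles again make 16 splits, too few for a share under 0.05, with 4 calls in the real one and at most 0 in the others, and the fit of the arms alone called 0 genes. Light against Wnt3a was picked out in the same way with 1 gene, and 2 of 60 splits gave as many, the real one included, the highest other count being 1, while its 16 swaps within profiles, too few for a share under 0.05, gave at most 1 call besides the real one.

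The 6 libraries with first component scores of -41.5 or lower had 74 genes at least 2-fold lower than in each of the other 14, which describes the grouping and does not test it, since the scores come from the same genes. All 6 stayed below the others when every library was thinned to 696463 reads, which argues against library depth. Of the 6, 3 had at least the other libraries' median number of genes detected at that depth, which argues against few detected genes as the cause. The 10 most abundant genes held 9.29% to 12.94% of reads in the 6 and 6.75% to 10.6% in the others. These ranges overlap but lie higher in the 6, so lower library complexity in this sense stays open. Among the treatment profiles, 0 had every library in the group, which argues against the profile, and the 3 plate columns held 2 of 8, 2 of 8 and 2 of 4 of these libraries (Fisher's exact test, two-sided p = 0.68). A handling batch that the labels do not give may account for the pattern and was not tested, and since every exact condition has 1 library, a response of single conditions also stays open.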

How the results depend on the processing

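The 6-library exclusion, the component covariate and the alternatives for sets were chosen after the data were seen. Counts follow in 1 order where a setting moved them: 3 d and 5 d against 0 d unstimulated, average sustained, sustained 3 d, sustained 5 d, 3 d ON against 1 d ON, Wnt3a against CHIR99021, light against CHIR99021, light against Wnt3a, and constant CHIR99021, Wnt3a and light. DESeq2 gave 626, 1251, 274, 113, 100, 271, 145, 736, 171, 616, 36 and 8, and 22 for genotype, 43 for 2 d OFF against 3 d ON, 3 for 1 d OFF against 1 d ON and 11 for the interaction. No filter on low counts gave 384, 661, 162, 54, 45, 70, 87, 389, 25, 639, 88 and 108, and 1, 17, 0 and 88 for those 4. The component covariate gave 683, 1834, 241, 74, 20, 377, 52, 1145, 334, 626, 0 and 0, with 21 for 2 d OFF against 3 d ON and 3 for the interaction. Without the 6 libraries the counts were 138, 235, 127, 0, 0, 192, 21, 51, 4, 1512 and 34 (light not estimable), with 1 for 2 d OFF against 3 d ON and 85 for the interaction. Without the wild-type libraries the first 9 were 2, 9, 0, 0, 0, 1, 2, 89 and 0. Without the inducer term the first 6 were 141, 311, 0, 0, 0 and 0. The arms alone gave 220 and 433 for time, 0 for average sustained, 15, 0, 31 and 0 for the comparisons from 3 d ON against 1 d ON to light against Wnt3a, and were not estimable for single days. RLE size factors kept every count within 1.5 times. Leaving out the 6 libraries left a lone Wnt3a and a lone wild-type library in the model of constant stimulation. It also left fewer residual degrees of freedom than the 3 of the main fit. The constant CHIR99021 and Wnt3a counts of that setting are therefore no measure of a stronger effect. In the interaction fit, that setting left light as the only inducer at 2 d OFF and fewer residual degrees of freedom than the 4 of the main fit. Its counts for 2 d OFF against 3 d ON and for the interaction are no measure of an effect either. In the full model, leaving out the 6 libraries left a lone library at unstimulated 0 d, unstimulated 5 d, 5 d ON and 2 d OFF. Except where a setting leaves out libraries or residual degrees of freedom, the cause was not tested.

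Leaving out 1 library at a time gave 17 to 75 and 32 to 425 calls for 3 d and 5 d against 0 d, 0 to 98 for average sustained, 0 to 0 for 3 d ON against 1 d ON, 1 to 5 for Wnt3a against CHIR99021, 6 to 167 for light against CHIR99021, 0 to 2 for light against Wnt3a, 0 to 445, 0 to 3 and 0 to 2 for constant CHIR99021, Wnt3a and light, and 0 to 1 for the interaction. The other comparisons stayed at 0. Withdrawn minus constant scores ran from -0.32 to 0.02 for genes higher at 5 d ON (above 0 only without CHIR99021 3 d ON), 0.14 to 0.43 for those lower, 0.23 to 0.42 for those rising with time (exact permutation p = 0.028 without Wnt3a 3 d ON) and -0.1 to 0.03 for those falling with time, the main values being -0.19, 0.3, 0.31 and -0.02. The last was above 0 in 6 of these fits, at 0.01 or 0.03. Scores under RLE, a prior count of 0.5 and a 4-fold gap (-0.4 and 0.51 for the 5 d sets) kept their direction and side of the threshold. Of 175 values of named IDs under the other settings, 133 stayed past the threshold, 42 did not and 0 changed direction, and of 200 with a library left out, 86, 114 and 0.

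No paired analysis was possible because the labels give no replicate numbers, and members of a profile differ in inducer or genotype, which the main model already holds as terms. The planned list tests with an estimated correlation and by fry were not run, as 0 IDs were paired with a symbol. A left-out library can leave 1 library in an arm, which is then assumed to vary like the other groups. Depth limits the Wnt3a 1 d ON library most (696463 reads, floor 4.21 CPM).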

Other observations

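The tests on the genes of 5 d ON were chosen after their values were seen, and the counts of other splits were set before. The 47 genes that were at least 4-fold higher in both 5 d ON libraries than in both unstimulated 5 d libraries had medians, relative to unstimulated 3 d, of 1.67 at 1 d and 3.51 at 3 d of CHIR99021. Under Wnt3a the medians were -0.11 and 0.87, and under light 0.25 and 1.12. After 1 d ON 1 d OFF they were 1.34 for CHIR99021, 0.74 for Wnt3a and 0 for light, and after 2 d OFF 1.71, 1.33 and -0.18. The 29 genes at least 4-fold lower stood at -3.08 and -2.47 in the 0 d libraries, at -2.62 at 3 d of CHIR99021 and at -0.29 and -0.67 at 3 d of Wnt3a and light. At 3 d of CHIR99021 the median of these 29 genes was therefore near its 0 d values. They were chosen as low at 5 d ON, with CHIR99021 among those libraries, so part of this likeness may be built in.

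The genes higher at 5 d ON were above unstimulated 3 d after CHIR99021 or Wnt3a was withdrawn. Under Wnt3a the values do not show that they stayed up. Their median was 0.07 (213 genes) and -0.11 (47 genes) at 1 d ON, and the values after withdrawal were higher. The 1 d ON values rest on a lone library, the shallowest (696463 reads, floor 4.21 CPM). A rise of weakly expressed genes could have been missed there. No light library entered the choice of genes, and light stood at 0.29 and 0.25 at 1 d ON, so its lower values after withdrawal are no test of a difference between inducers. The first component may account for part of the values after withdrawal. At 2 d OFF, both the CHIR99021 and the Wnt3a library (2 of 2) lie among the 6 with low component scores and the light library does not, so the component and the inducer cannot be told apart there. At 1 d OFF none of the 3 libraries lies among the 6. There, the lower of the CHIR99021 and Wnt3a medians over the 213 genes was below the highest unstimulated library, by a difference of -0.33. Over the 47 genes it was above it, by a difference of 0.31. In both sets that highest library was wild-type 0 d, itself among the 6. The unstimulated libraries above the gap stood at 0.21 or lower (213 genes) and 0.3 or lower (47 genes). Both 1 d OFF libraries were higher than these in both sets. Each inducer has a lone library there, so the explanation stays open.

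Across genes, the change from 3 d ON to 1 d ON 2 d OFF had a Pearson's r of 0.64 between CHIR99021 and Wnt3a, of -0.28 between CHIR99021 and light and of -0.38 between Wnt3a and light, with Spearman's rho of 0.64, -0.29 and -0.38 over 12190 genes, which are not independent replicates. These changes cross the gap on the first component in opposite directions, for light against the other inducers. The change from 1 d ON to 1 d ON 1 d OFF, in which no library lies below that gap, had a Pearson's r of 0.05, 0.09 and -0.01 for the same 3 pairs. The change from 1 d ON to 3 d ON, in which of these libraries only light 3 d ON lies below the gap, had a Pearson's r of 0.38, 0.1 and 0.12, so agreement between CHIR99021 and Wnt3a was not limited to changes that cross the gap.

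Other splits of the libraries bear on the remaining counts. For the average sustained comparison, 4 of 60 splits gave at least the 24 calls observed, the highest giving 93, so chance division cannot be excluded. The other splits place stimulated libraries, which keep their inducer term, in the unstimulated arm, so this share is no exact bound either. The cause of the split with 93 calls was not identified. For the comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real value for 3 d ON against 1 d ON was 3, with 1 of the 10 splits reaching it and a highest other count of 0. For genotype, for 1 d ON 2 d OFF against 3 d ON and for 1 d ON 1 d OFF against 1 d ON the real count and the highest other count were both 0, so 10 of 10 splits gave as many.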
